A study of Mus musculus and Rattus norvegicus with 24 samples.

How the data were processed

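RNA was measured in 24 animals, 3 in each of 8 groups: C57BL/6 mice and Sprague-Dawley rats, pMCAO or sham surgery, tissue taken at 2 h or 6 h. Per the labels, the left artery was occluded in rats and the right in mice, RNA was isolated with the RNeasy kit, its integrity number was above 7.5, and it was labelled with the WT PLUS kit for whole-transcript arrays. Groups and replicate numbers came from the sample titles. The titles, source names and descriptions give the same times, while a separate time label reads 2 h for every sample, so that label was not used. Each array is a separate animal, per the labels.

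The authors deposited a table of log2 expression values per species, to 2 decimals, with 12 arrays each. Per the submitters' processing notes the tools were oligo and limma, with no version. The background correction and normalization are not given in the sources used here. The deposited log2 values of the 2 h and 6 h arrays of a species have different medians, quartiles and minima (mouse minima 1.39 to 1.58 at 2 h and 0.84 to 1.00 at 6 h), while arrays of the same time nearly share theirs. Whether the times were processed apart is unknown, so pMCAO was compared with sham within a time. The files give no detection calls, so no gene was called absent. No 2 arrays of a table held equal values at more than 2.54% of clusters.

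The mouse table holds 41345 transcript clusters, of which the platform annotation gives 23521 a single gene symbol, 1814 several and 16010 none. The rat table holds 36685, with 18511, 575 and 17599. Genes tested were the symbols with a cluster of their own, taking the cluster with the highest mean over the 12 arrays where a symbol had several (1082 mouse and 291 rat symbols). This left 22180 mouse and 18166 rat genes. Of the mouse single-symbol clusters, 23328 had a gene ID in the RefSeq table of assembly GRCm38.p6, with 0 symbols differing. No genome build is named for the values, so no coordinates are given.

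For each species, limma 3.58.1 in R 4.3.3 fitted group means to all 12 arrays (8 residual degrees of freedom) and moderated the spread with eBayes at its default settings. Contrasts were pMCAO minus sham at 2 h and at 6 h, the difference of these contrasts, and sham at 6 h minus sham at 2 h. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p 0.05, and no fold limit. An exact permutation test of 3 against 3 animals cannot go below 0.1, so single genes rest on the model fitted across genes. Species effects were compared as the difference of the log2 fold changes over its standard error, with Welch-Satterthwaite degrees of freedom from the limma fits and Benjamini-Hochberg adjustment over 14204 matched symbols. Overlaps of calls were tested with one-sided Fisher's exact tests.

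The groups, tests, 19 pathway lists, 15 cell type lists, naming rule and the alternatives not marked as later choices were fixed before the data were examined. Of 631 listed genes, 559 were measured in mouse and 540 in rat. Lists share members, so their results are not separate. The reactive astrocyte list shares Timp1, Cd44, Sphk1, Hspb1, Cd14, Ptx3, Ptgs2 and Clcf1 with other pathway lists. The glucocorticoid-responsive list shares Cdkn1a, Per1, Ddit4 and Nfkbia with others. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Lists past the threshold numbered 10 in mouse at 2 h, 20 in mouse at 6 h, 13 in rat at 2 h and 17 in rat at 6 h, and the call also held with an estimated correlation for 1, 6, 0 and 7. For the change over time 15 lists passed in each species and 0 held. The rule named the 10 largest rises and falls past the threshold per pMCAO comparison, up to 4 members past it per pathway list, and the highest and lowest member past it per cell type list. It also named 5 each way for the other contrasts and 10 shared by the species, or all that passed where fewer did. It left out symbols starting with Gm and a digit, LOC, RGD, BC0, AA or AI and digits, Olfr, Olr, Or and digits, Vmn, Mir, Snor or n-R, or ending in Rik or Ps.

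The limma comparisons, the species difference, the list tests of the pMCAO comparisons and of the change over time, and the overlaps were tested on simulated arrays with the real gene means and spreads. Each gene was drawn independently, so these arrays held no inter-gene correlation. In the mouse 2 h comparison over 22180 genes, limma recovered 44.8% of the genes changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2, with 3.03% false calls. In the mouse 6 h comparison over 22180 genes the shares were 65.7%, 100% and 100%, with 7.81% false calls. In the rat 2 h comparison over 18166 genes they were 71.6%, 95.5% and 100%, with 2.73%, and in the rat 6 h comparison over 18166 genes 61.2%, 89.6% and 100%, with 5.11%. For the change over time they were 35.8%, 83.6% and 95.5% over 22180 mouse genes, with 7.74%, and 28.4%, 86.6% and 100% over 18166 rat genes, with 6.54%. For the species difference over 14204 genes they were 54.2%, 91.0% and 98.8% at 2 h, with 4.85%, and 56.2%, 82.8% and 100% at 6 h, with 3.74%. Cytokine and endothelial lists raised in turn by 0.3 passed the preset test at 2 h, at 6 h and for the change over time, among 33 lists in mouse and 34 in rat, with at most 1 other list called. With an estimated correlation they passed too, except the endothelial list in the rat change over time (adjusted p = 0.0602). Without inter-gene correlation, the other lists called do not measure false calls of the preset test on the real arrays. There, other splits of the samples called up to 6 and 14 lists in mouse and 11 and 12 in rat at 2 h and 6 h. Those splits mix the labels unevenly and keep part of the pMCAO effect, so they do not measure false calls either. With 200 genes raised by 2 on each side and 100 of them the same, the overlap found 100 at 2 h and 100 at 6 h between species over 14204 genes, 99 between times over 22180 mouse genes and 100 over 18166 rat genes. With none the same it found 0 in each. Alternatives covered normalization, the variance model, array weights, dim genes, the choice of clusters, a fold limit of log2 1, the replicate number as a block, single arrays left out, and fits to the compared arrays alone. A covariate of striatal markers and further alternatives for the overlaps were chosen after seeing the data.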

Results

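The series measured RNA on whole-transcript arrays in brain tissue of mice and rats after permanent occlusion of the middle cerebral artery (pMCAO), a model of ischaemic stroke in which a filament blocks the artery and is left in place. A 3 by 3 mm piece was taken from the penumbra, the tissue bordering the ischaemic core, at 2 h or 6 h, and from the matching area of sham-operated animals. Each of the 8 groups (mouse or rat, 2 h or 6 h, pMCAO or sham) held 3 animals with 1 array each, 24 arrays in all, and precision was limited by that number. Array medians on the log2 scale were 6.03 to 6.06 for mouse at 2 h and 5.92 to 5.96 at 6 h. For rat they were 6.67 to 6.75 at 2 h and 5.82 to 5.87 at 6 h, so pMCAO was compared with sham within a time. On the first principal component of the 6 rat arrays at 2 h, pMCAO replicate 2 lay at 25.9 and the other pMCAO arrays at 1.63 and 2.33. Transthyretin (Ttr), a choroid plexus transcript, ranged from 7.45 to 12.68 over the mouse arrays without following the groups.

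In mouse tissue at 2 h, the largest rises after pMCAO were in the inducible heat shock genes Hspa1a (4.29 ± 0.23, adjusted p = 1.08e-05) and Hspa1b (4.25 ± 0.24, adjusted p = 1.08e-05), given as log2 fold change ± SE over sham with n = 3 per group in limma. These are near-identical copies whose probes may not tell them apart, so their separate values are uncertain. The activity-dependent transcription factor Npas4 (3.08 ± 0.26, adjusted p = 0.000506) and the AP-1 genes Fosb (1.86), Fos (1.80) and Jun (1.35) rose. So did the chemokine Ccl3 (2.36), the matricellular protein gene Ccn1 (1.64), Ptgs2 (1.54), which encodes cyclooxygenase-2, and the co-chaperone Dnajb1 (1.43). Erdr1 was also higher than in sham (2.61 ± 0.41), with sham animals spread from 6.66 to 8.72 and pMCAO animals from 10.22 to 10.48. At 6 h it read 9.89 to 10.52 in sham and 10.03 to 10.83 after pMCAO, so only the 2 h sham arrays read low. The named falls were 9930111J21Rik2 (-0.68), Alox12b (-0.62), the glucocorticoid receptor co-chaperone Fkbp5 (-0.58), Rhou (-0.54), Trp53inp1 (-0.54), Lfng (-0.47), Slc25a13 (-0.46), Krt25 (-0.37) and Slc16a14 (-0.36). In all, 33 genes rose and 33 fell of 22180 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Among the falls, 18 were microRNA genes between Dlk1 and Dio3, a group chosen after its values were seen. Leaving out pMCAO replicate 1, 2 or 3 gave 41, 26 or 42 genes in place of 66. Leaving out sham replicate 1, 2 or 3 gave 29, 23 or 26, and the 6 arrays alone gave 23. Trend and robust eBayes gave 110, array weights 102, a striatal marker covariate chosen after seeing the data 42, all clusters 39 and a fold limit of log2 1 29. Of 28 named genes, 7 passed whichever array was left out: Hspa1a, Hspa1b, Npas4, Fosb, Fos, Jun and Ccn1. 9930111J21Rik2 lost the call without pMCAO replicate 2 or sham replicates 1 or 2 (limma adjusted p = 0.0528 to 0.0716). Alox12b, Fkbp5, Lfng, Rhou, Slc16a14 and Trp53inp1 lost the call without pMCAO replicates 1, 2 or 3 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0642 to 0.213). Ccl3 lost the call without pMCAO replicate 3 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0548 to 0.113). Dnajb1 lost the call without pMCAO replicates 1 or 2 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0785 to 0.117). Erdr1 lost the call without pMCAO replicates 1, 2 or 3 or sham replicate 2 (limma adjusted p = 0.0714 to 0.115). Krt25 lost the call without pMCAO replicates 1, 2 or 3 or sham replicates 1 or 3 (limma adjusted p = 0.0968 to 0.213). Ptgs2 lost the call without sham replicates 1 or 3 (limma adjusted p = 0.0568 to 0.0616). Slc25a13 lost the call without pMCAO replicates 1 or 3 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0799 to 0.142).

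Of 40 measured immediate early and activity-regulated genes, 12 rose, 0 fell and 28 did not pass, with 24 and 0 adjusted over the list alone. A median of 0.59 went with camera adjusted p = 4.13e-38, and adjusted p = 0.0185 with an estimated correlation. Of 21 measured heat shock and chaperone genes, 4 rose, 0 fell and 17 did not pass, with 7 and 0 adjusted over the list alone. A median of 0.17 went with camera adjusted p = 2.59e-13, and adjusted p = 0.106 with an estimated correlation. Of 23 measured genes of matrix remodelling, fibrinolysis and vascular growth, 3 rose, 0 fell and 20 did not pass, with 4 and 0 adjusted over the list alone, such as Adamts1 (1.10) and Thbs1 (0.75). A median of 0.07 went with camera adjusted p = 6.25e-05, and adjusted p = 0.106 with an estimated correlation. Of 26 measured cytokines and chemokines, 2 rose, 0 fell and 24 did not pass, with 3 and 0 adjusted over the list alone, Il1a (0.79) beside Ccl3. A median of 0.09 went with camera adjusted p = 0.00104, and adjusted p = 0.123 with an estimated correlation. Of 20 measured genes of NF-kB feedback, adhesion and innate sensing, 1 rose, 0 fell and 19 did not pass, with 6 and 0 adjusted over the list alone, Nfkbiz (0.51) among them. A median of 0.17 went with camera adjusted p = 3.7e-07, and adjusted p = 0.106 with an estimated correlation. Of 16 measured glucocorticoid-responsive genes, 0 rose, 1 fell and 15 did not pass, with 1 and 3 adjusted over the list alone, Fkbp5 being the member that fell. A median of -0.19 went with camera adjusted p = 0.000156, and adjusted p = 0.242 with an estimated correlation. The inward-rectifier channel gene Kcnj2 (0.73), the clock-related Nfil3 (0.56) and the reactive astrocyte gene Emp1 (0.42) rose singly. Among cell type markers, those of oligodendrocyte precursors were lower by the preset test (0 rose and 0 fell of 7, 0 and 3 adjusted over the list alone, median -0.23, camera adjusted p = 0.00175, and adjusted p = 0.241 with an estimated correlation). Those of oligodendrocytes were lower (0 rose and 0 fell of 13, 0 and 0 adjusted over the list alone, median -0.08, camera adjusted p = 0.0353, and adjusted p = 0.887 with an estimated correlation). Those of meningeal fibroblasts were lower (0 rose and 0 fell of 10, 0 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.0321, and adjusted p = 0.438 with an estimated correlation). Neutrophil markers were higher (0 rose and 0 fell of 13, 0 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 0.00591, and adjusted p = 0.241 with an estimated correlation). Adamts1 and Thbs1 lost the call without any 1 array other than pMCAO replicate 3 (limma adjusted p = 0.0579 to 0.14). Emp1, Il1a, Nfil3 and Nfkbiz lost the call without any 1 of the 6 arrays (limma adjusted p = 0.057 to 0.237). Kcnj2 lost the call without any 1 array other than pMCAO replicate 1 (limma adjusted p = 0.0744 to 0.127).

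In rat tissue at 2 h, 6 genes rose and 6 fell of 18166 tested (limma, Benjamini-Hochberg). The rises were in the AP-1 gene Fos (2.44 ± 0.34, adjusted p = 0.0182), Ccn1 (1.52), Tnfrsf11b (1.04), which encodes osteoprotegerin, Plat (0.94), which encodes tissue plasminogen activator, Jun (0.79) and Qrfprl (0.67). The falls were in Fkbp5 (-0.81 ± 0.10, adjusted p = 0.00897), Fam43a (-0.70), Zbtb16 (-0.66), the Notch target gene Hes1 (-0.59), and the microRNA genes Mir186 (-1.03) and Mir376a (-0.83), which lay outside the naming rule and were named after their values were seen. Mir376a was dim, with means of 3.05 after pMCAO and 3.88 in sham against array minima of 2.57 to 2.73. Of 38 measured immediate early and activity-regulated genes, 2 rose, 0 fell and 36 did not pass, with 19 and 0 adjusted over the list alone. A median of 0.63 went with camera adjusted p = 3.59e-28, and adjusted p = 0.0984 with an estimated correlation. Of 16 measured glucocorticoid-responsive genes, 0 rose, 2 fell and 14 did not pass, with 0 and 8 adjusted over the list alone, Fkbp5 and Zbtb16 being the members that fell. A median of -0.29 went with camera adjusted p = 4.67e-08, and adjusted p = 0.155 with an estimated correlation. The pMCAO animals differed among themselves: Npas4 read 12.74 in replicate 2 against 8.73 and 10.92 in the others, and did not pass (3.71 ± 0.69, limma adjusted p = 0.102). Without sham replicate 2 the count of 12 was 6. Without sham replicate 3 it was 0 in limma with 822 genes at an unadjusted p under 0.05, and with the 6 arrays alone it was 44. Array weights gave 65, trend and robust eBayes 28, all clusters 4 and a fold limit of log2 1 also 4. Ccn1, Fkbp5, Qrfprl and Tnfrsf11b lost the call without sham replicate 3 (limma adjusted p = 0.0536). Fam43a lost the call without pMCAO replicate 3 or sham replicates 2 or 3 (limma adjusted p = 0.0699 to 0.149). Fos and Plat lost the call without sham replicates 1, 2 or 3 (limma adjusted p = 0.0635 to 0.145). Hes1 lost the call without pMCAO replicates 2 or 3 or sham replicates 2 or 3 (limma adjusted p = 0.0599 to 0.136). Jun lost the call without sham replicates 2 or 3 (limma adjusted p = 0.0559 to 0.0647). Zbtb16 lost the call without pMCAO replicates 1, 2 or 3 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0559 to 0.149).

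Several rat lists moved at 2 h by the preset test though few members passed singly. Of 18 measured heat shock and chaperone genes, 0 rose, 0 fell and 18 did not pass, with 5 and 0 adjusted over the list alone. A median of 0.15 went with camera adjusted p = 1.69e-09, and adjusted p = 0.0984 with an estimated correlation. Of 26 measured cytokines and chemokines, 0 rose, 0 fell and 26 did not pass, with 3 and 0 adjusted over the list alone. A median of 0.17 went with camera adjusted p = 4.67e-08, and adjusted p = 0.171 with an estimated correlation. Of 22 measured genes of matrix remodelling, fibrinolysis and vascular growth, 2 rose, 0 fell and 20 did not pass, with 7 and 0 adjusted over the list alone, Ccn1 and Plat being those that rose. A median of 0.14 went with camera adjusted p = 2.94e-08, and adjusted p = 0.0984 with an estimated correlation. Of 19 measured genes of NF-kB feedback, adhesion and innate sensing, 0 rose, 0 fell and 19 did not pass, with 1 and 0 adjusted over the list alone. A median of 0.19 went with camera adjusted p = 2.69e-05, and adjusted p = 0.171 with an estimated correlation. Reactive astrocyte genes were higher (0 rose and 0 fell of 21, 1 and 0 adjusted over the list alone, median 0.15, camera adjusted p = 0.000599, and adjusted p = 0.221 with an estimated correlation). Cholesterol genes were higher (0 rose and 0 fell of 17, 0 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.0283, and adjusted p = 0.534 with an estimated correlation). Neutrophil markers were higher (0 rose and 0 fell of 12, 3 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00014, and adjusted p = 0.0984 with an estimated correlation). Tight junction genes were lower (0 rose and 0 fell of 10, 0 and 0 adjusted over the list alone, median -0.11, camera adjusted p = 0.0466, and adjusted p = 0.314 with an estimated correlation). Astrocyte markers were lower (0 rose and 0 fell of 10, 0 and 1 adjusted over the list alone, median -0.05, camera adjusted p = 0.0239, and adjusted p = 0.292 with an estimated correlation). So were oligodendrocyte precursor markers (0 rose and 0 fell of 7, 0 and 0 adjusted over the list alone, median -0.10, camera adjusted p = 0.0278, and adjusted p = 0.314 with an estimated correlation). Striatal neuron markers were lower too (0 rose and 0 fell of 11, 0 and 0 adjusted over the list alone, median -0.22, camera adjusted p = 0.000225, and adjusted p = 0.21 with an estimated correlation).

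**Figure D1:**
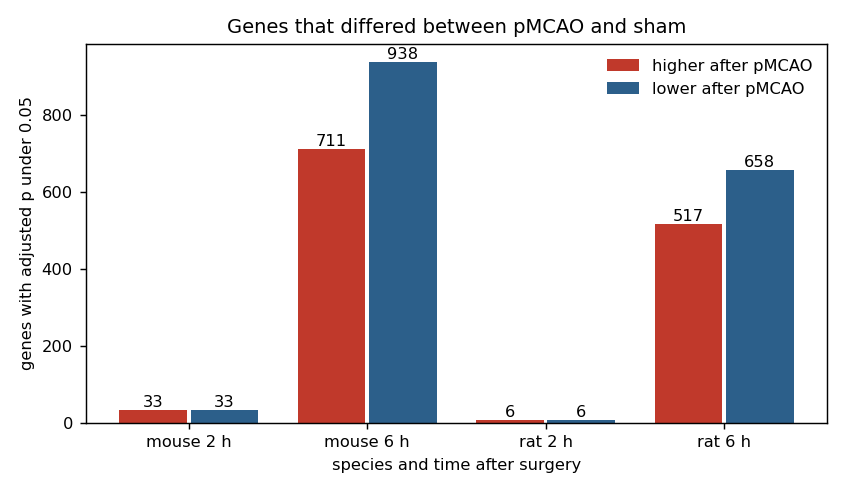
Number of genes with an adjusted p under 0.05 (limma) on the vertical axis, higher (red) or lower (blue) after pMCAO than after sham surgery, for each species and time on the horizontal axis, with 3 animals per group. Few genes passed at 2 h (33 and 33 in mouse, 6 and 6 in rat) and more at 6 h (711 and 938 in mouse, 517 and 658 in rat).

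In mouse tissue at 6 h, Hspa1a (4.36 ± 0.23, adjusted p = 9.4e-06), its near-identical copy Hspa1b (4.21 ± 0.24) and the chemokine Ccl3 (3.99 ± 0.36, adjusted p = 0.000254) rose the most. The inhibitory myeloid receptor gene Lilrb4a (2.88), the stress-response genes Gadd45b (2.33) and Gadd45g (2.02), the AP-1 gene Fosb (2.02), Ptgs2 (2.00), Npas4 (2.00) and the lipopolysaccharide co-receptor Cd14 (1.83) also rose. The largest falls among the symbols the naming rule allows were in the dopamine receptor Drd2 (-1.64 ± 0.41, adjusted p = 0.0355), Gpr52 (-1.30), Krt17 (-0.87), Selplg (-0.85 ± 0.08, adjusted p = 0.000254), Sh3rf2 (-0.85), the blood-brain barrier organic anion transporter Slco1a4 (-0.82 ± 0.11, adjusted p = 0.00209), Dach1 (-0.82), Zkscan16 (-0.80), Zfp97 (-0.79) and Lrrn3 (-0.79). For Drd2, Sh3rf2 and Dach1, sham replicate 2 (7.11, 5.99 and 5.46) lay near the highest pMCAO array (6.86, 5.91 and 5.38), as for the striatal marker mean given below. The other shams read 8.64 and 8.85, 6.76 and 7.05, and 6.28 and 6.46. For Gpr52 sham replicate 2 was the lowest sham (7.75), above the pMCAO arrays (6.84 to 7.03). For the other listed falls it was not the single lowest sham. Of 22180 genes, 711 rose and 938 fell (limma, Benjamini-Hochberg), with 847 and 811 after quantile normalization and 681 and 862 after median centring, and 49 rises and 11 falls reached a log2 fold change of 1. Leaving out pMCAO replicate 2 or 3 gave 1042 or 951 genes in place of 1649. Leaving out sham replicate 1, 2 or 3 gave 1047, 861 or 616, and the 6 arrays alone gave 246. Trend and robust eBayes gave 2574, and a striatal marker covariate chosen after seeing the data 68. Of 85 named genes, 54 passed whichever array was left out. Dach1, Drd2 and Sh3rf2 lost the call without pMCAO replicates 1, 2 or 3 or sham replicates 1 or 3 (limma adjusted p = 0.0511 to 0.16). Krt17 lost the call without pMCAO replicates 1 or 3 or sham replicates 1 or 2 (limma adjusted p = 0.0678 to 0.0963). Zfp97 lost the call without pMCAO replicates 2 or 3 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0557 to 0.123).

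Of 40 measured immediate early and activity-regulated genes, 23 rose, 0 fell and 17 did not pass, with 26 and 0 adjusted over the list alone. A median of 0.59 went with camera adjusted p = 2.24e-24, and adjusted p = 0.0187 with an estimated correlation. Of 21 measured heat shock and chaperone genes, 12 rose, 0 fell and 9 did not pass, with 14 and 1 adjusted over the list alone, such as Dnajb1 (1.45) and Hspb1 (1.45) beside the Hspa1 pair. A median of 0.38 went with camera adjusted p = 4.35e-14, and adjusted p = 0.0524 with an estimated correlation. Of 26 measured cytokines and chemokines, 7 rose, 0 fell and 19 did not pass, with 11 and 0 adjusted over the list alone, such as Il1a (1.44), Il1b (1.10) and Ccl4 (0.80). A median of 0.25 went with camera adjusted p = 2.79e-09, and adjusted p = 0.0128 with an estimated correlation. Of 23 measured genes of matrix remodelling, fibrinolysis and vascular growth, 10 rose, 0 fell and 13 did not pass, with 16 and 0 adjusted over the list alone, such as Ccn1 (1.57), Adamts9 (1.09) and Angpt2 (0.86). A median of 0.46 went with camera adjusted p = 4.66e-11, and adjusted p = 0.0128 with an estimated correlation. Of 22 measured reactive astrocyte genes, 10 rose, 0 fell and 12 did not pass, with 16 and 1 adjusted over the list alone, such as the oncostatin M receptor gene Osmr (1.28). Some of the rises, such as Hspb1, Cd14 and Ptgs2, also count in other lists. A median of 0.54 went with camera adjusted p = 8.1e-14, and adjusted p = 0.0128 with an estimated correlation. Of 24 measured hypoxia and glycolysis genes, 5 rose, 0 fell and 19 did not pass, with 7 and 0 adjusted over the list alone, such as Adm (1.16) and Vegfa (0.52). A median of 0.17 went with camera adjusted p = 3.25e-05, and adjusted p = 0.0311 with an estimated correlation. Of 20 measured genes of NF-kB feedback, adhesion and innate sensing, 6 rose, 0 fell and 14 did not pass, with 6 and 0 adjusted over the list alone, such as Rel (0.58) and Tnfaip6 (0.54). A median of 0.23 went with camera adjusted p = 3.89e-08, and adjusted p = 0.0371 with an estimated correlation. Ccl4 lost the call without pMCAO replicates 2 or 3 or sham replicate 2 (limma adjusted p = 0.0509 to 0.0549). Il1b lost the call without sham replicate 3 (limma adjusted p = 0.0641). Rel lost the call without any 1 array other than pMCAO replicate 1 (limma adjusted p = 0.0573 to 0.109). Tnfaip6 lost the call without any 1 of the 6 arrays (limma adjusted p = 0.0539 to 0.114). Vegfa lost the call without pMCAO replicate 2 or sham replicate 3 (limma adjusted p = 0.0541 to 0.0646).

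Among p53 and apoptosis genes in mouse at 6 h (6 rose and 1 fell of 19, 7 and 1 adjusted over the list alone, median 0.16, camera adjusted p = 0.000336, and adjusted p = 0.13 with an estimated correlation) were Cdkn1a (1.27) and Fas (0.82). Among antioxidant genes (2 rose and 0 fell of 17, 3 and 0 adjusted over the list alone, median 0.12, camera adjusted p = 0.00152, and adjusted p = 0.0595 with an estimated correlation) was Hmox1 (1.37), which encodes haem oxygenase 1. Among cholesterol genes (4 rose and 0 fell of 17, 10 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 3.84e-07, and adjusted p = 0.189 with an estimated correlation) was Mvd (0.49). Glucocorticoid-responsive genes were higher (6 rose and 0 fell of 16, 8 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.000155, and adjusted p = 0.152 with an estimated correlation), with Errfi1 (0.93) and Pdk4 (0.76), while Fkbp5 read -0.26 ± 0.10 (limma adjusted p = 0.122). The unfolded protein and stress list (5 rose and 1 fell of 27, 7 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.00263, and adjusted p = 0.32 with an estimated correlation) included Chac1 (0.70) and Ddit3 (0.60). Voltage-gated channel genes (2 rose and 8 fell of 34, 2 and 14 adjusted over the list alone, median -0.13, camera adjusted p = 0.000417, and adjusted p = 0.0595 with an estimated correlation) included Scn1a (-0.61), Kcnv1 (-0.54) and Kcnq3 (-0.49). Glutamate and GABA-A receptor genes (0 rose and 2 fell of 23, 0 and 2 adjusted over the list alone, median -0.10, camera adjusted p = 0.0094, and adjusted p = 0.13 with an estimated correlation) included Grik2 (-0.43). Interferon-stimulated genes (3 rose and 0 fell of 18, 3 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.0404, and adjusted p = 0.152 with an estimated correlation) included Irf7 (0.35). Chac1 lost the call without sham replicates 2 or 3 (limma adjusted p = 0.056 to 0.0616). Kcnv1 lost the call without any 1 array other than pMCAO replicate 1 (limma adjusted p = 0.0827 to 0.129).

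Of 10 striatal neuron markers in mouse at 6 h, 10 lay below sham and 3 fell (0 rose and 3 fell of 10, 0 and 10 adjusted over the list alone, median -0.68, camera adjusted p = 4.08e-06, and adjusted p = 0.231 with an estimated correlation), Drd2 the most. The mean of the markers was 7.49 in sham replicate 2 against 8.30 and 8.52 in the other shams and 7.25 to 7.45 after pMCAO. With that mean as a covariate, an alternative chosen after seeing the data, 68 genes passed in the comparison, 64 of them among the 1649 without it. All 1649 kept their direction, with a median absolute log2 fold change of 0.36 against 0.38 and a median SE of 0.119 against 0.081. Neutrophil markers (2 rose and 0 fell of 13, 4 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00715, and adjusted p = 0.152 with an estimated correlation) included Retnlg (1.19) and Fpr2 (0.88). Meningeal fibroblast markers (2 rose and 0 fell of 10, 2 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 0.00152, and adjusted p = 0.145 with an estimated correlation) included Aldh1a2 (0.75) and Mgp (0.39). The homeostatic microglial receptor P2ry12 (-0.78 ± 0.09, adjusted p = 0.00121) fell while Fcrls (0.37) rose. Among endothelial markers Cdh5 (0.58) rose and Abcb1a (-0.44) fell, and the cortical neuron gene Neurod6 (-0.73) fell while Rtn4rl2 (0.39) rose. Neuron markers were slightly lower (0 rose and 1 fell of 14, 0 and 1 adjusted over the list alone, median -0.09, camera adjusted p = 0.0279, and adjusted p = 0.164 with an estimated correlation). Oligodendrocyte markers were slightly higher (0 rose and 1 fell of 13, 4 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.018, and adjusted p = 0.556 with an estimated correlation). Abcb1a lost the call without pMCAO replicate 3 or sham replicates 1 or 2 (limma adjusted p = 0.061 to 0.0949). Cdh5 lost the call without pMCAO replicates 1 or 2 or sham replicates 2 or 3 (limma adjusted p = 0.062 to 0.102). Fcrls lost the call without pMCAO replicates 1 or 2 or sham replicates 1 or 2 (limma adjusted p = 0.0523 to 0.0619). Mgp lost the call without any 1 array other than pMCAO replicate 3 (limma adjusted p = 0.0552 to 0.0964).

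In rat tissue at 6 h, the chemokine genes Ccl3 (4.13 ± 0.37, adjusted p = 0.000133), Ccl4 (2.78) and Ccl2 (2.64) rose together with the activity-regulated genes Npas4 (3.91 ± 0.69, adjusted p = 0.00708), Fos (3.71 ± 0.34, adjusted p = 0.000153), Egr2 (2.90), Fosb (2.83) and Junb (2.46) and with Gadd45g (3.29) and Gadd45b (2.46). The largest falls among the symbols the naming rule allows were in the barrier transporter Slco1a4 (-1.90 ± 0.17, adjusted p = 0.000124), C1h9orf85 (-1.69), the efflux pump Abcg2 (-1.56 ± 0.23, adjusted p = 0.00268), the microglial receptor Gpr34 (-1.50 ± 0.18, adjusted p = 0.000925), Bmp4 (-1.35), Tmem74 (-1.29), Prom1 (-1.20), Neurod1 (-1.12), the clock output gene Dbp (-1.08) and Abcb1a (-1.08 ± 0.11, adjusted p = 0.000225), which encodes P-glycoprotein. Of 18166 genes, 517 rose and 658 fell (limma, Benjamini-Hochberg), with 588 and 610 after quantile normalization and 598 and 553 after median centring. The count of 1175 was 550 without sham replicate 1, 552 without sham replicate 2 363 with the 6 arrays alone and 123 at a fold limit of log2 1. Of 78 named genes, 60 passed whichever array was left out. C1h9orf85 lost the call without pMCAO replicates 1, 2 or 3 or sham replicates 1, 2 or 3 (limma adjusted p = 0.0622 to 0.115). Neurod1 lost the call without sham replicates 1 or 2 (limma adjusted p = 0.0512 to 0.0612).

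Of 38 measured immediate early and activity-regulated genes, 33 rose, 0 fell and 5 did not pass, with 37 and 0 adjusted over the list alone. A median of 1.47 went with camera adjusted p = 7.71e-44, and adjusted p = 0.0327 with an estimated correlation. Of 18 measured heat shock and chaperone genes, 9 rose, 0 fell and 9 did not pass, with 15 and 0 adjusted over the list alone, such as Hspb1 (1.33) and Hsph1 (0.97). A median of 0.37 went with camera adjusted p = 7.92e-14, and adjusted p = 0.0327 with an estimated correlation. Rat Hspa1a and Hspa1b had no array cluster of their own. Of 26 measured cytokines and chemokines, 9 rose, 0 fell and 17 did not pass, with 13 and 0 adjusted over the list alone. A median of 0.36 went with camera adjusted p = 5.53e-12, and adjusted p = 0.0534 with an estimated correlation. Of 19 measured genes of NF-kB feedback, adhesion and innate sensing, 11 rose, 0 fell and 8 did not pass, with 14 and 0 adjusted over the list alone, such as Rel (1.37), Socs3 (1.37) and Nfkbia (1.17). A median of 0.58 went with camera adjusted p = 3.03e-13, and adjusted p = 0.0327 with an estimated correlation. Of 22 measured genes of matrix remodelling, fibrinolysis and vascular growth, 9 rose, 1 fell and 12 did not pass, with 12 and 1 adjusted over the list alone, such as Timp1 (2.32), Adamts9 (2.14) and Plat (1.80). A median of 0.38 went with camera adjusted p = 4.37e-11, and adjusted p = 0.0327 with an estimated correlation. Of 17 measured cholesterol synthesis and uptake genes, 8 rose, 0 fell and 9 did not pass, with 14 and 0 adjusted over the list alone, such as Idi1 (1.07), Stard4 (1.01) and Insig1 (0.95). A median of 0.39 went with camera adjusted p = 6e-14, and adjusted p = 0.0327 with an estimated correlation. Of 21 measured reactive astrocyte genes, 8 rose, 0 fell and 13 did not pass, with 11 and 0 adjusted over the list alone, Osmr (2.05) among them. A median of 0.51 went with camera adjusted p = 2.3e-11, and adjusted p = 0.0327 with an estimated correlation. 

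Among other rat lists at 6 h, the metallothionein gene Mt1 (1.93) and Hmox1 (1.65) rose within the antioxidant list (3 rose and 1 fell of 19, 5 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.00542, and adjusted p = 0.238 with an estimated correlation), and Gclm (-0.60) fell. Hypoxia genes (7 rose and 0 fell of 24, 9 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 6.07e-05, and adjusted p = 0.119 with an estimated correlation) included Pfkfb3 (1.02). Clock genes (3 rose and 2 fell of 15, 5 and 3 adjusted over the list alone, median 0.18, camera adjusted p = 0.0246, and adjusted p = 0.316 with an estimated correlation) included Nfil3 (1.75), Per1 (0.85) and Dbp. Unfolded protein and stress genes (6 rose and 0 fell of 27, 6 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.000302, and adjusted p = 0.152 with an estimated correlation) included Atf4 (0.66) and Hspa5 (0.63). The p53 and apoptosis list (4 rose and 0 fell of 18, 4 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.00627, and adjusted p = 0.113 with an estimated correlation) held Gadd45a (1.00). The glucocorticoid-responsive list (6 rose and 1 fell of 16, 6 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.000153, and adjusted p = 0.217 with an estimated correlation) held Errfi1 (1.47). Tight junction genes (0 rose and 2 fell of 10, 0 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.0165, and adjusted p = 0.202 with an estimated correlation) included Ocln (-0.92) and Cldn12 (-0.59). Endothelial markers (0 rose and 4 fell of 11, 2 and 5 adjusted over the list alone, median -0.27, camera adjusted p = 0.00602, and adjusted p = 0.395 with an estimated correlation) that fell ranged from Emcn (-0.71) to Abcb1a. Neutrophil markers (2 rose and 0 fell of 12, 6 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 2.61e-05, and adjusted p = 0.0358 with an estimated correlation) included Mmp8 (1.04) and S100a9 (0.99). Among microglial markers (3 rose and 4 fell of 12, 4 and 6 adjusted over the list alone, median -0.16, camera adjusted p = 0.692, and adjusted p = 0.861 with an estimated correlation) Itgam (0.69) rose and Gpr34 fell. Striatal markers were slightly above sham (0 rose and 0 fell of 11, 0 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.0395, and adjusted p = 0.414 with an estimated correlation). Emcn lost the call without sham replicate 1 (limma adjusted p = 0.0576). Itgam lost the call without any 1 array other than pMCAO replicate 2 (limma adjusted p = 0.0846 to 0.112). Mmp8 lost the call without any 1 array other than pMCAO replicate 3 (limma adjusted p = 0.0515 to 0.125). Per1 lost the call without pMCAO replicate 1 or sham replicates 2 or 3 (limma adjusted p = 0.0523 to 0.0567). Pfkfb3 lost the call without sham replicates 1, 2 or 3 (limma adjusted p = 0.0532 to 0.0539). S100a9 lost the call without sham replicate 2 (limma adjusted p = 0.0544).

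**Figure D2:**
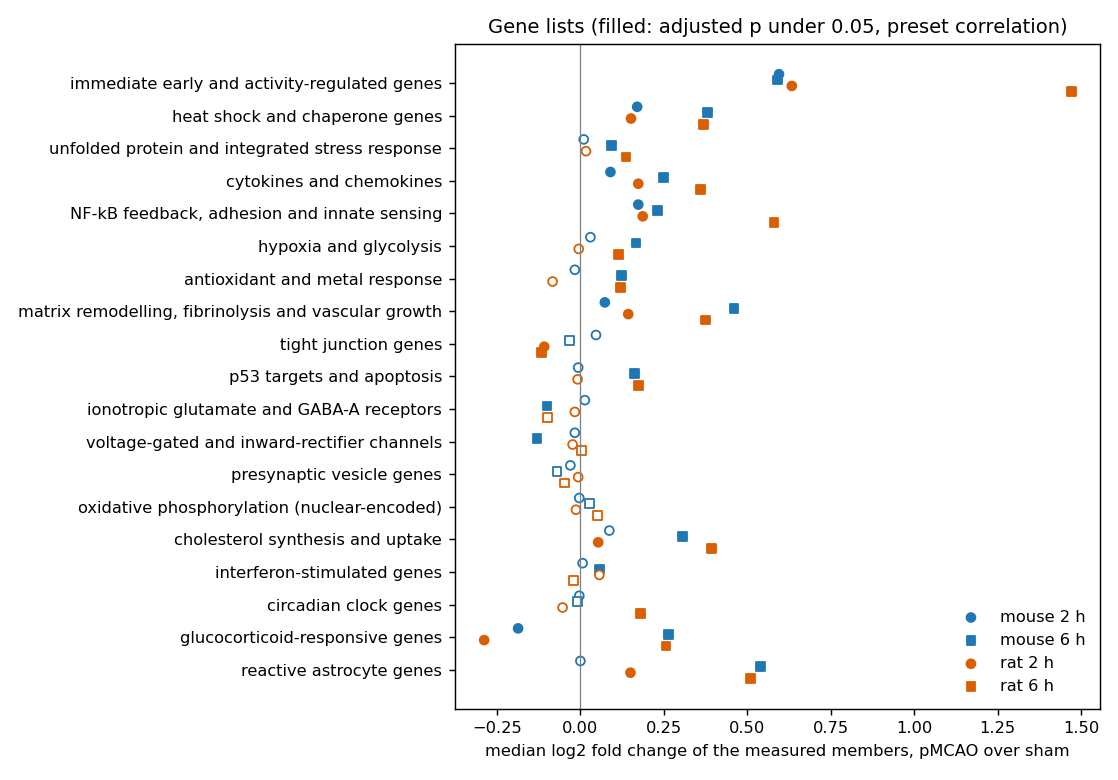
Median log2 fold change of the measured members, pMCAO over sham, on the horizontal axis for each pathway list on the vertical axis, in mouse (blue) and rat (orange) at 2 h (circles) and 6 h (squares), filled where the camera adjusted p was under 0.05 with the preset correlation. The immediate early list lay highest in rat at 6 h (1.47), and the glucocorticoid-responsive list lay below 0 at 2 h and above 0 at 6 h.

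The change of the pMCAO effect from 2 h to 6 h, the interaction of surgery and time, was tested within each species. In mouse the effect on the stress-response gene Gadd45b (1.60 ± 0.23, adjusted p = 0.0379), Cdkn1a (1.38), Dyrk3 (1.26), Cyp1b1 (1.23) and Angpt2 (1.05) was higher at 6 h (limma). That on the neuropeptide Y receptor Npy1r (-1.22), Flrt2 (-1.09), Ddit4l (-1.09), Zfp40 (-0.98) and the transporter Slco1a4 (-0.90 ± 0.15, adjusted p = 0.0463) was lower. In rat Gadd45b (2.09 ± 0.25, adjusted p = 0.00982), Ccl4 (1.99), Mt1 (1.98), Osmr (1.83) and C3h11orf96 (1.59) were higher at 6 h. There Slco1a4 (-1.92 ± 0.23, adjusted p = 0.0103), Tmem74 (-1.35), Tnfrsf11b (-1.29), Flrt2 (-1.07) and Abcb1a (-1.01) were lower. The pMCAO effect on glucocorticoid-responsive genes changed upwards by the preset test in mouse (2 rose and 0 fell of 16, 7 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 1.91e-09, and adjusted p = 0.101 with an estimated correlation). It did so in rat (1 rose and 0 fell of 16, 11 and 0 adjusted over the list alone, median 0.64, camera adjusted p = 3.95e-14, and adjusted p = 0.121 with an estimated correlation). A change of the effect can come from sham as well as pMCAO animals, as in 2 mouse genes picked after their values were seen. Pdk4 read 7.27 to 7.51 in sham at 2 h and 6.14 to 6.56 at 6 h, against 6.91 to 7.24 and 7.09 to 7.21 after pMCAO. Dyrk3 read 7.35 to 7.81 and 5.85 to 6.33 in sham, against 7.24 to 7.46 and 6.94 to 7.3 after pMCAO. Rat Tnfrsf11b and Flrt2 were higher in sham at 6 h than at 2 h, by 1.11 and 1.09 after median centring of the arrays. Processing that differed between the times may contribute to that. How the remaining genes divide was not examined. In all, 19 genes were higher and 19 lower in mouse, and 30 higher and 12 lower in rat (limma, Benjamini-Hochberg), with a mouse split of 27 and 17 after quantile normalization and 22 and 19 after median centring. With the striatal marker covariate, chosen after seeing the data, 0 mouse genes passed in limma and 2368 had an unadjusted p under 0.05. Other settings gave 351 in mouse and 121 in rat (trend and robust eBayes), 250 and 103 (without the dim genes), 15 and 7 (all clusters), and 13 and 22 (fold limit of log2 1), and array weights gave 82 in rat. The mouse count of 38 was 3, 12 and 12 without 2 h pMCAO replicate 1, 2 or 3, and 5, 0 and 1 without 2 h sham replicate 1, 2 or 3. It was 85, 13 and 1 without 6 h pMCAO replicate 1, 2 or 3 and 16, 2 and 6 without 6 h sham replicate 1, 2 or 3. The count of 0 stood beside 2687 genes at an unadjusted p under 0.05 in limma. None of the 10 named mouse genes passed whichever array was left out, each losing the call without 5 to 11 of the 12 arrays, at a limma adjusted p of at most 0.119. The rat count of 42 was 23 and 11 without 2 h pMCAO replicate 1 or 3, 11, 18 and 19 without 2 h sham replicate 1, 2 or 3. It was 19 and 140 without 6 h pMCAO replicate 1 or 2, and 20, 11 and 12 without 6 h sham replicate 1, 2 or 3. Of 10 named rat genes, 5 passed whichever array was left out (Gadd45b, Mt1, C3h11orf96, Slco1a4 and Tnfrsf11b). Tmem74 lost the call without 2 h sham replicate 1 (limma adjusted p = 0.0515), and Ccl4, Osmr, Flrt2 and Abcb1a lost it without 6 to 9 arrays (limma adjusted p = 0.0508 to 0.0895).

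Calls at the times overlapped within a species. Both comparisons rest on the same estimate of each gene's spread, and genes are not independent. The expected counts and exact p-values below may therefore overstate the overlap. In mouse 25 of the 33 genes that rose at 2 h also rose at 6 h against 1.06 for independent lists (one-sided Fisher's exact test, p = 3.2e-31), and 18 of 33 that fell also fell against 1.40 (exact p = 9.09e-17). In rat 4 of 6 rises were shared against 0.171 (exact p = 9.29e-06). No fall was shared there, 0 against 0.217 (exact p = 1), while 36 falls and 7 rises were shared without 6 h pMCAO replicate 3, 17 and 14 with array weights, and at most 4 falls in the other settings run. Genes called at both times with opposite signs, named after their values were seen, were Ddit4l in mouse (0.57 at 2 h and -0.51 at 6 h) and Fam43a (-0.70 and 0.37) and Zbtb16 (-0.66 and 0.50) in rat. The 43 shared mouse genes became 25 without 2 h pMCAO replicate 2, 23, 22 and 22 without 2 h sham replicate 1, 2 or 3 and 22 without 6 h sham replicate 3, 27 over all clusters and 13 at a fold limit of log2 1. The 4 in rat became 7 without 2 h pMCAO replicate 1 or 2, 2, 2 and 0 without 2 h sham replicate 1, 2 or 3, and 7, 15 and 43 without 6 h pMCAO replicate 1, 2 or 3. They became 13 with trend and robust eBayes, 8 without the dim genes, 2 at a fold limit of log2 1 and 1 over all clusters.

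**Figure D3:**
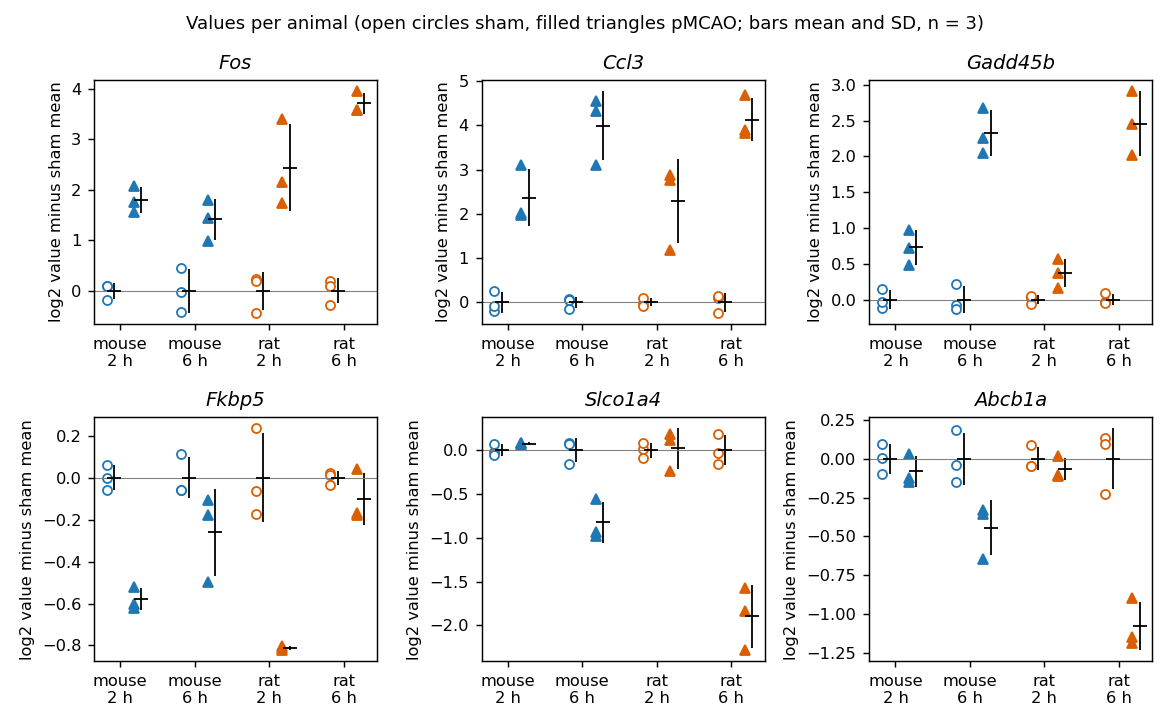
Log2 value of each animal minus the mean of its sham group on the vertical axis, for 6 genes, with sham (open circles) and pMCAO (filled triangles) animals by species and time on the horizontal axis, and the mean and SD of 3 animals beside them. Slco1a4 fell by 0.82 in mouse and by 1.90 in rat at 6 h, and Fkbp5 fell by 0.58 in mouse and by 0.81 in rat at 2 h.

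Mouse and rat were compared over 14204 genes matched by symbol. Fisher's exact test treats genes as independent, which they are not, so its p-values may overstate the overlap. At 2 h, Fos, Ccn1 and Jun rose in both, 3 shared rises against 0.0106 for independent lists (one-sided Fisher's exact test, p = 9.6e-08). Fkbp5 and Mir376a fell in both, 2 shared falls against 0.0114 (exact p = 5.2e-05). Mir376a (-1.11 in mouse and -0.83 in rat) was named after its values were seen, and in rat it lay near the array minima. At 6 h, 156 rises were shared against 16.8 (exact p = 1.13e-112) and 159 falls against 28.5 (exact p = 1.34e-77). At that time 0 genes were called in both in opposite directions. The shared 6 h rises and falls with the largest effects by rule were Ccl3, Gadd45b, Fosb, Gadd45g, Ptgs2, Npas4, Nptx2, Ccn1, Atf3 and Jun, all rises. The log2 fold changes correlated across genes at 0.50 (Pearson) at each time, and at 0.30 and 0.37 by rank, and genes are not independent replicates. The 5 genes shared at 2 h became 3 without any single mouse array or rat sham replicate 2, and 0 without rat sham replicate 3. They became 22 with array weights, 9 with trend and robust eBayes, 3 with the mean of a gene's clusters and 2 at a fold limit of log2 1. The 315 shared at 6 h became 208 without mouse pMCAO replicate 2, 179 and 142 without mouse sham replicate 2 or 3, and 175 and 183 without rat sham replicate 1 or 2. Trend and robust eBayes gave 566, the filter on dim genes 529 and the fold limit 22.

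At 2 h the species differed for 2 genes: Tnfrsf11b (0.02 in mouse, 1.04 in rat, difference -1.02 ± 0.14, adjusted p = 0.00507) and Plat (0.06 in mouse, 0.94 in rat, difference -0.88 ± 0.15, adjusted p = 0.0449). At 6 h the effect was more positive in mouse for 154 genes and in rat for 169, with 182 and 180 after quantile normalization and 135 and 194 after median centring. Trend and robust eBayes gave 531 genes at 6 h, array weights 200 and a fold limit of log2 1 45. It was larger in rat for Fos (1.41 in mouse, 3.71 in rat, difference -2.29 ± 0.41, adjusted p = 0.00673). The AP-1 and early genes also included Egr2 (0.61 in mouse, 2.90 in rat, difference -2.29 ± 0.53, adjusted p = 0.0249) and Junb (0.61 in mouse, 2.46 in rat, difference -1.84 ± 0.33, adjusted p = 0.00851). A larger rat effect was found too for Ccl4 (0.80 in mouse, 2.78 in rat, difference -1.98 ± 0.27, adjusted p = 0.00051) and Nr4a1 (0.58 in mouse, 2.37 in rat, difference -1.79 ± 0.46, adjusted p = 0.0391). It was lower in rat for Abcg2 (0.00 in mouse, -1.56 in rat, difference 1.56 ± 0.24, adjusted p = 0.00673) and Gpr34 (-0.18 in mouse, -1.50 in rat, difference 1.32 ± 0.22, adjusted p = 0.00455). Lower rat effects were also found for Ctla2a (1.26 in mouse, -0.18 in rat, difference 1.44 ± 0.21, adjusted p = 0.00129) and Bmp4 (0.04 in mouse, -1.35 in rat, difference 1.39 ± 0.25, adjusted p = 0.0136). The last of the 5 was Lyzl4 (0.87 in mouse, -0.36 in rat, difference 1.24 ± 0.22, adjusted p = 0.00646). The species also differed in array design and occluded side. The 2 h count was 4 with array weights, and 1 with quantile normalization, median centring or the fold limit. It was also 1 without mouse pMCAO replicate 1, mouse sham replicate 1 or 3, rat pMCAO replicate 2 or rat sham replicate 1. It was 0 without rat pMCAO replicate 3, rat sham replicate 2 or rat sham replicate 3, where 692, 612 and 422 genes had an unadjusted p under 0.05 from the limma fits. Plat lost the call without mouse pMCAO replicates 1 or 3 or mouse sham replicates 1 or 3 or rat pMCAO replicates 2 or 3 or rat sham replicates 1, 2 or 3 (limma adjusted p = 0.054 to 0.23). Tnfrsf11b lost the call without rat pMCAO replicate 3 or rat sham replicates 2 or 3 (limma adjusted p = 0.0656 to 0.079). The 6 h count of 323 was 213 without mouse sham replicate 1, 184 without rat sham replicate 1 and 141 without rat sham replicate 2. Egr2 lost the call without mouse pMCAO replicate 3 or mouse sham replicate 1 or rat pMCAO replicates 1 or 3 or rat sham replicates 2 or 3 (limma adjusted p = 0.0518 to 0.0718). Nr4a1 lost the call without mouse pMCAO replicates 2 or 3 or mouse sham replicates 1 or 3 or rat pMCAO replicates 1 or 3 or rat sham replicates 2 or 3 (limma adjusted p = 0.0537 to 0.116).

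**Figure D4:**
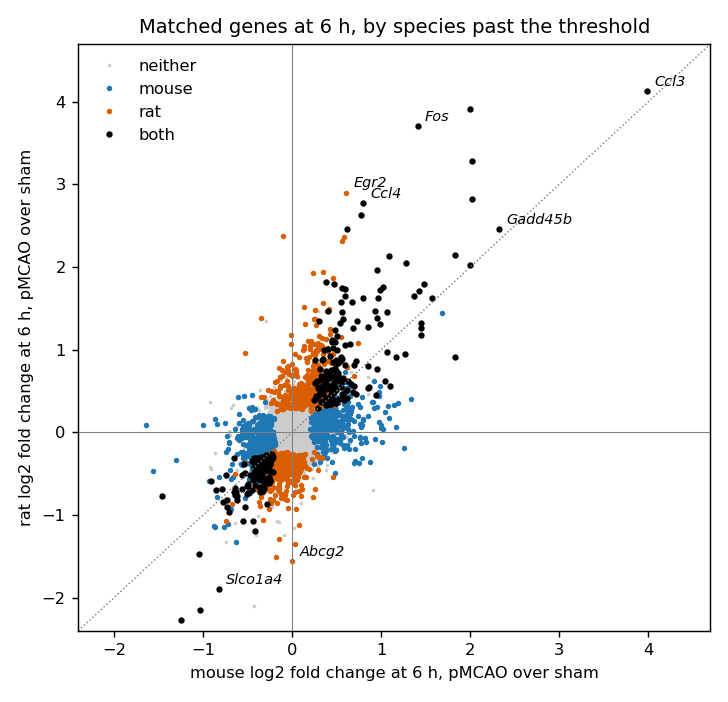
Log2 fold change, pMCAO over sham, at 6 h in mouse (horizontal axis) and rat (vertical axis) for the 14204 matched genes, coloured by the species in which the gene passed the threshold, with equal effects on the dotted line. Ccl3 lay near the line (3.99 and 4.13), Fos above it (1.41 and 3.71) and Slco1a4 below 0 in both (-0.82 and -1.90).

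The sham groups at 6 h and 2 h serve as background. The median of all genes differed by -0.16 in mouse and by -0.81 in rat. Genes were chosen and tested on the deposited values, given first, and the value after median centring of the arrays follows. In mouse the thioredoxin-interacting protein gene Txnip (-1.29 and -1.16), the glucocorticoid-induced kinase gene Sgk1 (-1.23 and -1.10), Nfkbia (-1.21 and -1.08), Dyrk3 (-1.50 and -1.37) and Pramel27 (-1.42 and -1.29) were lower at 6 h. There Erdr1 (2.41 and 2.54), H4c8 (1.41 and 1.54), Kir3dl1 (1.04 and 1.17), Akr1c20 (1.03 and 1.16) and Spink11 (1.02 and 1.15) were higher. In rat Taar7g (-2.51 and -1.67), Ttr (-2.34 and -1.50), Ppp4r3cl2 (-2.22 and -1.38), Klk1c6 (-2.18 and -1.34) and Vom1r107 (-2.16 and -1.33) were lower. The rat genes higher on the deposited values were the osteopontin gene Spp1 (0.47 and 1.30), Tnfrsf11b (0.27 and 1.11) and Flrt2 (0.25 and 1.09). After centring 10 of the 10 mouse genes and 7 of the 8 rat genes passed, Ttr not (limma adjusted p = 0.342). Rat Taar7g, Ppp4r3cl2, Klk1c6 and Vom1r107 were dim, with sham means of 4.09 to 5.39 at 2 h and 1.93 to 3.21 at 6 h, while the minima of the rat sham arrays were 2.61 to 2.73 at 2 h and 1.02 to 1.09 at 6 h, a larger drop than that of the median. Mouse Pramel27, H4c8, Kir3dl1, Akr1c20 and Spink11 were dim too, with 2 h sham means of 2.64 to 3.75. The differences of all genes named for sham, like the counts, cannot be separated from any processing that differed between the times. Rat Ttr read 11.03 in 2 h sham replicate 3 against 6.88 and 6.93 in the others. In the test on the deposited values, Flrt2 lost the call without 2 h sham replicates 2 or 3 or 6 h sham replicates 2 or 3 (limma adjusted p = 0.0823 to 0.162). Spp1 lost the call without 2 h sham replicates 1 or 3 or 6 h sham replicate 3 (limma adjusted p = 0.0547 to 0.0773). Tnfrsf11b lost the call without 2 h sham replicates 2 or 3 or 6 h sham replicate 1 (limma adjusted p = 0.112 to 0.137). Ttr lost the call without 2 h sham replicate 3 or 6 h sham replicates 1, 2 or 3 (limma adjusted p = 0.0726 to 0.256). By camera 2 lists were higher and 5 lower in mouse, and 12 higher and 1 lower in rat, of which 0 held with an estimated correlation. In the 12 rat lists the median and mean lay below 0, opposite to the test, which compares a list with the other genes. The counts of 932 higher and 7526 lower genes in mouse and 3 and 17782 in rat (limma) are those of the deposited values. After quantile normalization over the 12 arrays they were 1573 and 1507 in mouse and 1394 and 1477 in rat, and after median centring 1790 and 2634 in mouse and 1789 and 1586 in rat.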

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

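The tests of other splits of the arrays, and those weighed for the barrier transporters and the striatal markers, were chosen after the results were seen. The effect of pMCAO differed between 2 h and 6 h for 38 mouse genes (limma): Gadd45b (1.60), Cdkn1a (1.38), Dyrk3 (1.26), Cyp1b1 (1.23), Angpt2 (1.05), Npy1r (-1.22), Flrt2 (-1.09), Ddit4l (-1.09), Zfp40 (-0.98) and Slco1a4 (-0.90) by rule, as log2 fold change at 6 h minus that at 2 h. In 3 of 100 regroupings of the arrays, the real one included, as many genes passed, with a highest other count of 97. Of these splits 92 mixed the 6 h labels, which puts the 6 h effect into the spread: genes called at 6 h had a median residual SD of 0.183 against 0.097 with the real labels, and at most 1 gene passed. The other 7 kept or exchanged the 6 h labels whole, 2 of them gave as many genes, and they are too few for a share under 0.05. In rat 42 genes differed: Gadd45b (2.09), Ccl4 (1.99), Mt1 (1.98), Osmr (1.83), C3h11orf96 (1.59), Slco1a4 (-1.92), Tmem74 (-1.35), Tnfrsf11b (-1.29), Flrt2 (-1.07) and Abcb1a (-1.01) by rule. There 4 of 100 regroupings gave as many, with a highest other count of 601. The 92 splits that mixed the 6 h labels gave at most 4 genes, with a median residual SD of 0.232 against 0.123, and of the 7 others 3 gave as many, again too few for a share under 0.05. The regroupings at or above the real counts kept the true labels at 6 h and mixed those at 2 h, which points to a structure of the samples: the 6 h effect stays in them whole.

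The effects of the species differed for 2 genes at 2 h, Tnfrsf11b (-1.02) and Plat (-0.88), and for 323 at 6 h, as mouse minus rat log2 fold change. Among the latter were Fos (-2.29), Egr2 (-2.29), Ccl4 (-1.98), Junb (-1.84) and Nr4a1 (-1.79), more positive in rat, and Abcg2 (1.56), Ctla2a (1.44), Bmp4 (1.39), Gpr34 (1.32) and Lyzl4 (1.24), more positive in mouse. In 10 of 100 regroupings at 2 h and 5 of 100 at 6 h the count was as large, with highest other counts of 175 and 3096. These shares decide nothing about chance. The 84 splits that mixed the labels of both species, which puts their effects into the spread, gave at most 1 gene at 2 h and 3 at 6 h. The 14 that kept or exchanged the labels of 1 species whole carry its effect and gave as many in 8 cases at 2 h (at most 10 genes) and 3 at 6 h (at most 1179), which points to a structure of the samples. The 1 other exchanged pMCAO and sham in all rat arrays, so that the effects of the species add, and gave the highest counts. Splits with both species whole are too few for a share under 0.05.

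Each comparison of 3 against 3 arrays allows 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave a count as large. Every other split mixed the labels, which puts the difference between the groups into the spread. Low gene counts in those splits therefore follow from any large difference, whatever its cause, and decide nothing about chance. The real and highest other counts were 66 and 0 in mouse at 2 h, 1649 and 0 in mouse at 6 h, 12 and 0 in rat at 2 h, 1175 and 1 in rat at 6 h, 8458 and 0 for mouse sham and 17785 and 0 for rat sham. For gene lists they were 10 and 6, 20 and 14, 13 and 11, and 17 and 12 in the same order of pMCAO comparisons.

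Transcript clusters with no gene named were outside the comparisons, and some passed the threshold when all clusters were fitted with limma: 9 of 16010 in mouse at 2 h, 319 in mouse at 6 h, 1 of 17599 in rat at 2 h and 268 in rat at 6 h. The shares at 6 h, 1.99% and 1.52%, lay below those of named clusters, 3.62% and 3.12%.

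Slco1a4 and Abcb1a, transporters of the blood-brain barrier, fell at 6 h in both species, and Abcg2 and Slco1c1 in rat (-1.56 and -0.89), the set being picked after these values were seen. The other endothelial markers had a median of -0.21 in rat (quartiles -0.34 and 0.11) against -1.32 for the 4 transporters (upper quartile -1.03). In mouse it was 0.02 (quartiles -0.13 and 0.11) against -0.40 (upper quartile -0.27). Of these other markers 0 rose, 2 fell and 6 lay below sham of 9 in rat, and 1 rose, 0 fell and 6 lay below sham of 12 in mouse. Fewer endothelial cells cannot be weighed by this. Transporters picked for their falls, some of them from the endothelial list, lie below the remaining markers by choice. Probes of the rat array alone cannot be told apart from a fall of the set: 2 of the 4 fell on the mouse array, the 2 that were picked with that in view, and Abcg2 (0.00) and Slco1c1 (-0.36) did not pass there (limma adjusted p = 0.983 and 0.112). The 4 transporters kept a median below 0 at 6 h under quantile normalization (-1.28 in rat and -0.39 in mouse) and median centring (-1.29 and -0.40). An effect of pMCAO on these transcripts, the difference the design names, stays open and was not tested further.

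The striatal markers were lower as a list in mouse at 6 h (median -0.68). A different share of striatum in the dissected piece may account for it, since the 3 sham arrays spread over 1.03 in mean marker value while pMCAO differed from sham by -0.78. Fewer neurons of every kind, as the source of a fall of that size, is argued against by the neuron markers. Their median was -0.09 (quartiles -0.14 and -0.03). A smaller loss is not excluded, since in their mean the 3 pMCAO arrays lay below every sham array. An effect of the occlusion on striatal neurons stays open as untested, and the rat markers had a median of 0.09 at 6 h.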

How the results depend on the processing

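Alternatives to the overlaps other than the fold limit, dim filter, quantile normalization and replicate block, and the striatal covariate, were chosen after seeing the data. No gene or list named reversed its direction past the threshold under any alternative run, and 82 of 251 gene calls passed under every one, with 0 of 10 in rat at 2 h, 0 of 10 for the mouse change over time and 0 of 2 for the species difference at 2 h. The fold limit is among these alternatives and ends every call below log2 1, so the 82 do not measure dependence on the processing alone. Whichever single array was left out, 54 of 85 named calls in mouse and 60 of 78 in rat held at 6 h. Counts that moved by over 1.5 times follow, and the cause was not tested unless given.

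With trend and robust eBayes, mouse 2 h gave 110 genes, mouse 6 h 2574, rat 2 h 28, the change over time 351 in mouse and 121 in rat. It gave 531 for the species difference at 6 h, 9 and 566 for the species overlap at 2 h and 6 h, and 13 for the overlap of times in rat. With array weights the counts were 102 in mouse and 65 in rat at 2 h, 82 for the rat change over time, 31 for the overlap of times in rat, 4 and 200 for the species difference at 2 h and 6 h, and 22 for the species overlap at 2 h. Without the dim genes, which leaves fewer genes to adjust for, the change over time gave 250 in mouse and 103 in rat, the overlap of times in rat 8 and the species overlap at 6 h 529. With all clusters, which adds tests, the counts were 39 in mouse and 4 in rat at 2 h, 15 and 7 for the change over time, 27 and 1 for the overlap of times and 34847 for rat sham. Species differences cannot be run on clusters, which carry no shared symbol. The mean of a gene's clusters gave a species overlap of 3 at 2 h. Quantile normalization gave 3080 for mouse sham, 2871 for rat sham and 1 for the species difference at 2 h, and median centring 4424, 3375 and 1.

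A fold limit of log2 1, which can only remove calls, left 29 and 60 genes in mouse and 4 and 123 in rat at 2 h and 6 h, and 13 and 22 for the change over time. It left 48 and 4132 for sham, 13 and 2 for the overlap of times, 1 and 45 for the species difference and 2 and 22 for the species overlap. With the 6 compared arrays alone the counts were 23 and 246 in mouse and 44 and 363 in rat. This leaves fewer arrays for the spread, which does not account for the higher rat count at 2 h (44 in place of 12), and the cause was not tested. The striatal covariate left 42 at 2 h, 68 at 6 h and 0 for the change over time in mouse, where limma gave 2368 genes at an unadjusted p under 0.05. Of the 1649 calls at 6 h 64 stayed past the threshold and 1649 kept their direction, the median absolute log2 fold change going from 0.38 to 0.36 and the median SE from 0.081 to 0.119, so the calls ended mostly with the larger SE. With an estimated correlation 1, 6, 0 and 7 lists passed in mouse 2 h, mouse 6 h, rat 2 h and rat 6 h.

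Replicate numbers showed no clear pairing of the animals: deviations of same-numbered arrays correlated between -0.12 and 0.33, not all above 0.1. With 3 arrays per group this cannot exclude a pairing. Of the 3 pMCAO and 3 sham arrays of a time, 0 and 0 correlated best with their own number in mouse at 2 h, 1 and 2 in mouse at 6 h, 1 and 1 in rat at 2 h and 2 and 2 in rat at 6 h, as a hint from the data, so not every array did. With the replicate block the change over time gave 15 in mouse and 25 in rat, the species difference at 2 h 1 and the species overlap at 2 h 3, with other counts within 1.5 times.

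Leaving out single arrays gave 23 to 42 genes in mouse and 0 to 16 in rat at 2 h, 616 to 1368 and 550 to 1268 at 6 h, 0 to 85 and 11 to 140 for the change over time. It gave 6511 to 6954 and 17609 to 17658 for sham, 22 to 39 and 0 to 43 for the overlap of times, 0 to 3 and 141 to 386 for the species difference, and 0 to 7 and 142 to 342 for the species overlap. Lists past the threshold ranged from 9 to 10 and 17 to 21 in mouse and 10 to 15 and 15 to 19 in rat. The files give no signal over background, so what dim genes limit cannot be stated.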

Other observations

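The zinc finger, protocadherin beta and microRNA families below, and all their tests, were chosen after the values were seen. Zinc finger genes lay lower than other genes by the preset test at both times. At 6 h 37 fell and 6 rose of 398 in mouse (median -0.10, camera adjusted p = 0.00017, and adjusted p = 0.0632 with an estimated correlation). Likewise 35 fell and 2 rose of 263 in rat (median -0.12, camera adjusted p = 2.52e-06, and adjusted p = 0.0632 with an estimated correlation), adjusted over the 12 tests of 3 families. At 2 h 0 fell and 1 rose in mouse (median -0.05, camera adjusted p = 0.000942, and adjusted p = 0.0778 with an estimated correlation), and 0 fell and 0 rose in rat (median -0.06, camera adjusted p = 3.04e-05, and adjusted p = 0.0642 with an estimated correlation). Of 22 protocadherin beta genes, which encode neuronal cell-surface adhesion proteins, 14 fell and 22 lay below sham in mouse at 6 h (median -0.39, camera adjusted p = 1.84e-13, and adjusted p = 0.0109 with an estimated correlation). In rat 2 of 19 fell (median -0.21, camera adjusted p = 0.00827, and adjusted p = 0.125 with an estimated correlation). At 2 h 0 fell in either species, with a median of -0.05 in mouse (camera adjusted p = 0.0606, and adjusted p = 0.288 with an estimated correlation) and -0.14 in rat (camera adjusted p = 0.000356, and adjusted p = 0.0632 with an estimated correlation). The medians of both families stayed below 0 at 2 h and 6 h under quantile normalization and median centring, the protocadherin median at -0.41 and -0.39 in mouse at 6 h. Members of both families resemble each other in sequence, and whether their probes are independent was not tested.

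Of the microRNA genes that lie between Dlk1 and Dio3 in the mouse gene order, 18 of 43 fell in mouse at 2 h (median -0.65, camera adjusted p = 1.86e-46, and adjusted p = 0.00967 with an estimated correlation), and Mir543, Mir495 and Mir154 fell by 2.12, 1.62 and 1.57. The 3 pMCAO arrays lay below every sham array in the mean of the cluster (difference -0.68, exact permutation p = 0.1, the smallest possible), as they did with smaller differences for other microRNA genes of like brightness (-0.08, exact p = 0.1) and for neuron markers (-0.03, exact p = 0.1), and the median was -0.63 under quantile normalization and -0.64 under median centring. Of 140 other microRNA genes of like brightness (above the cluster's lower quartile) 3 fell and 0 rose. Their median was 0.0117, so a fall of like size was not common to them. Lower signal of all microRNA probes cannot be weighed by this. The cluster was picked for its fall, and without detection calls unexpressed genes, which could not fall, were not set apart. Fewer neurons, as the source of the cluster's fall, is argued against by a median of -0.0567 for the neuron markers. On the rat array 44 microRNA genes of that order were measured, only part of them among the 43 of mouse. Their median in rat at 2 h was -0.74, and all 44 lay below sham while 1 of 44 fell singly (camera adjusted p = 2.06e-32, and adjusted p = 0.0632 with an estimated correlation). For the genes measured in both species this argues against probes of the mouse array alone. At 6 h the medians were -0.36 in mouse, where 16 of 43 fell (camera adjusted p = 3.95e-12, and adjusted p = 0.0632 with an estimated correlation), and -0.56 in rat, where 3 of 44 fell (camera adjusted p = 4.76e-07, and adjusted p = 0.278 with an estimated correlation) and the mean of pMCAO replicate 3 (5.88) lay above every sham (5.66 to 5.76). An effect of pMCAO on these transcripts, the difference the design names, stays open as untested, and the neighbouring Meg3 and Rian read 0.18 ± 0.07 and 0.11 ± 0.06 in mouse at 2 h and did not pass.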
